A study of Oryzias latipes with 18 samples.

How the data were processed

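RNA sequencing of medaka testis covered 18 libraries, with 3 biological replicates in each of 6 groups formed by 2 lineages and 3 PFOS concentrations. Per the submitters' processing notes, RNA was extracted with a Zymo Quick RNA/DNA kit, libraries were made with the NEBNext Ultra II RNA kit and sequenced at Novogene, and reads passed through fastp 0.23.2, STAR 2.7.7a and DESeq2 1.34.0. The genome build, annotation release, read counter and strand setting are not given in the sources used here, so values of overlapping or antisense genes and of close paralogs carry that uncertainty. The signal values deposited by the authors are gene read counts divided by 1 size factor per library, as DESeq2 normalizes them, for 22941 genes, of which 14992 have a name.

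The table was checked for whole reads: within a tolerance of 0.01, 100% of the values were whole multiples of 1 step per library. Those steps gave back whole reads for the count-based tools. Recovered reads ranged from 23.7 to 47.7 M reads per library, normalized totals from 20.2 to 36.9 M and genes above 0 from 20250 to 22384. Correlations between replicates on the log2 scale ran from 0.927 to 0.971, apart from 0.771 and 0.779 for the library labelled control lineage PFOS 0.002 replicate 2.

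Genes with a mean value of at least 10 over the libraries were kept, which left 18792. limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) with 6 group means, an intensity trend and robust moderation. Two-sided tests were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. There were 12 comparisons: each PFOS dose against none in each lineage, any PFOS effect in each lineage (moderated F test), the lineages at each dose and averaged over doses, and the interaction of lineage and dose at each dose. Gene lists, 25 in all and written from general knowledge of the tissue, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, where at least 5 members were measured. This held for 23 lists. Lists for spermatogonia, Leydig cells, DNA methylation and chromatin modifiers, fatty acid oxidation, cholesterol synthesis, p53 and apoptosis, and blood cells had no call in any comparison. Groups, comparisons, lists, tests and the rule for naming genes were set before the data were examined.

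Genes are named by this rule: among genes past the threshold with a symbol and a mean value of at least 50, the 10 largest rises and the 10 largest falls in each comparison (5 and 5 for 0.002 mg/L, for the lineages at 0.002 and 0.02 mg/L and for their average). Added to these are at most 10 members of the lists that pass, and at most 4 list examples. Where fewer than 5 genes pass, the 5 named genes with the smallest p are given as not passing. Values of marker genes per library were chosen after they were seen.

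Alternatives set beforehand were a pseudocount of 5, no filter, TMM scaling, a fit to the compared groups alone, the replicate number as a block, a fold threshold of 1 on the log2 scale, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each replicate in turn. Fits to the 17 libraries without the library labelled control lineage PFOS 0.002 replicate 2, with their own alternatives, were added after seeing the data. In them that group has n = 2, and counts from fits that leave 1 library in it are not given. The gene filter, the size factors and the mean value for naming in these fits came from all 18 libraries. The library left out thus still shaped which genes were tested and named. The results for 1 gene are not reported here.

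The procedure was tested on simulated data with the spread of these libraries and 200 of 18792 genes changed. Genes were drawn independently of each other, so false calls from genes that vary together were not measured. At 0.02 mg/L in the control lineage limma recovered 2% of genes changed 2-fold and 43% of genes changed 4-fold from 18 libraries, with 5 unchanged genes called. From 17 libraries it recovered 30% and 80%, with 6 unchanged genes called. For the interaction at 0.02 mg/L from 17 libraries it recovered 6% and 53%. DESeq2 called 38 to 51 unchanged genes in the same simulations, so its counts are given beside those of limma and edgeR only.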

Results

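Testes of medaka were compared between 2 lineages of fish, each kept for 21 days in water without PFOS or with PFOS at 0.002 or 0.02 mg/L. The control lineage had no ancestral exposure. The BPA lineage descended from ancestors exposed as embryos to bisphenol A at 10 µg/L, 4 generations earlier. PFOS, perfluorooctane sulfonate, is a persistent fluorinated surfactant. Each of the 6 groups had 3 biological replicates, which gave 18 libraries. Read numbers recovered from the normalized values ranged from 23.7 to 47.7 M reads per library, and 18792 genes passed the filter on low values. Group values below are means of normalized read counts ± SD with n = 3. Differences are on the log2 scale ± SE, from limma, with Benjamini-Hochberg adjusted p over all genes tested.

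The library labelled control lineage PFOS 0.002 replicate 2 stood apart from the other 17. Its level of the oocyte and ovary list was 8.46 on the log2 scale relative to the others, which ranged from -0.58 to 1.07. Egg-coat and oocyte genes were abundant in it: zpax1 reached 210333 normalized reads, zp3f.1 205014 and org 167011, against a highest value of 2639, 2249 and 919 elsewhere. Several testis lists were low in the same library. The spermatid and flagellum list stood at -2.90 (others -0.31 to 0.49), the meiotic prophase list at -2.27 (others -0.35 to 0.42), the Sertoli cell list at -2.68 (others -0.98 to 0.62) and the Leydig cell list at -2.40 (others -0.94 to 0.41). The spermatogonia list at -0.26 (others -0.29 to 0.46) and the piRNA pathway at -0.26 (others -0.35 to 0.37) lay inside the range of the others, as did the germ cell gene ddx4 with 28213 normalized reads (others 21983 to 49655). The spermatogonial marker id4, a member of the first list, had 4.05 normalized reads there, against 25.1 to 281 in the others. The list level thus does not show that spermatogonia were retained. The male-determining gene dmy had 489 normalized reads in the same library, against 1465 to 4469 in the others. Mitochondrial mRNA took 0.448% of its reads, against 1.96% to 5.78%. Its 27.4 M reads lay inside the range of the others. The number of genes called by limma in each of the 12 comparisons is therefore given from all 18 libraries and again from the 17 without it, a choice made after seeing the data. List tests and DESeq2 counts are from 18 libraries unless stated.

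**Figure D1:**
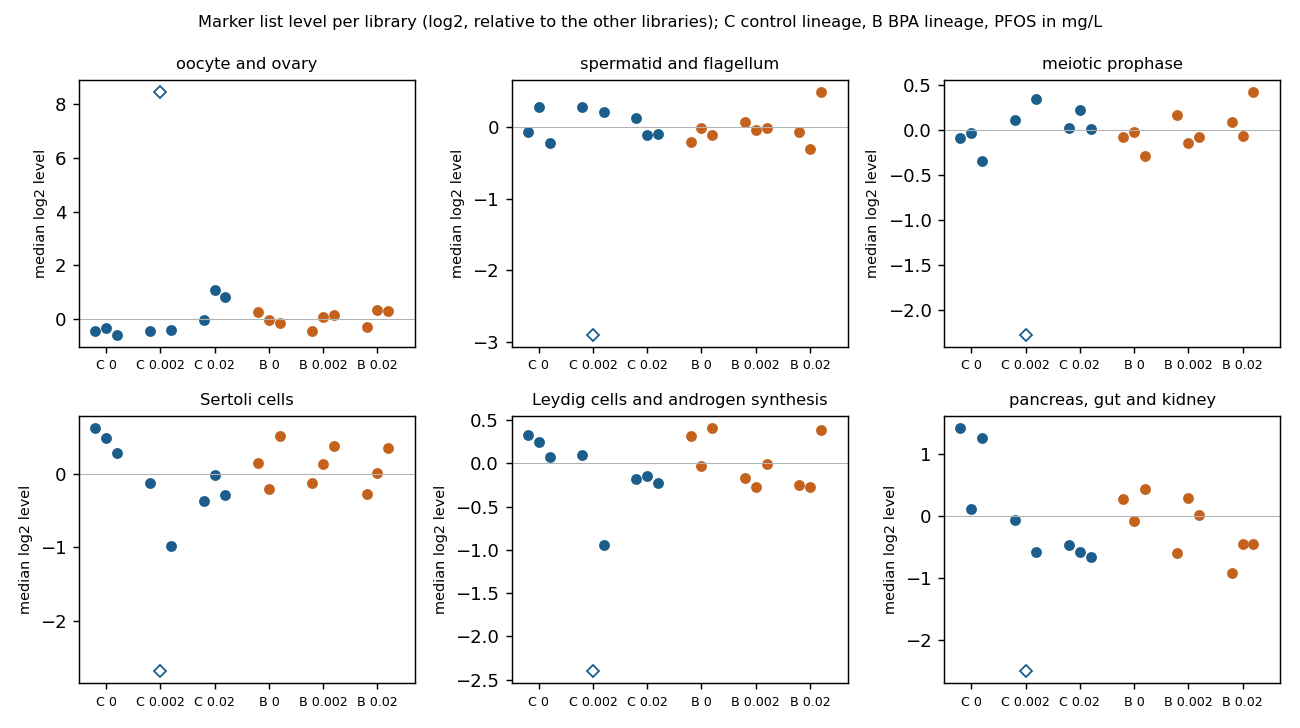
Median log2 level of 6 marker gene lists in each library, relative to the other libraries, with the control lineage (C) and the BPA lineage (B) on the x axis, each at the 3 PFOS levels in mg/L. The open diamond is the library labelled control lineage PFOS 0.002 replicate 2, at 8.46 for the oocyte and ovary list and at -2.90 for the spermatid and flagellum list.

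The libraries of the control lineage at 0 mg/L, the reference of most comparisons, also differed among themselves. Their level of the pancreas, gut and kidney list was 1.43, 0.12 and 1.26 in replicates 1, 2 and 3, against -0.91 to 0.44 in the 14 libraries outside this group and the one that stood apart. The intestinal cadherin cdh17 had 2578, 84.2 and 6201 normalized reads in these 3 libraries. The lipoprotein gene apoa4a was high in replicate 1 alone (32012), and the kidney cotransporter slc12a3 in replicate 3 alone (31800).

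The first comparison asked what 0.002 mg/L PFOS did in the control lineage. The largest rise among named genes was that of the immediate-early gene c-fos, from 65.6 ± 26.5 to 4660 ± 2918 normalized reads, a log2 difference of 6.05 ± 1.10 (adjusted p = 0.0208). It was 6.17 ± 1.37 in the 17-library fit (adjusted p = 0.0343), and each library at 0.002 mg/L exceeded each library at 0 mg/L. In the BPA lineage c-fos had 4751, 1824 and 165 normalized reads without PFOS. Each exceeded the 35.0, 79.3 and 82.4 of the control lineage at 0 mg/L. The MAP kinase phosphatase dusp2 rose by 4.57 and the transcriptional regulator mecom by 3.03, and in the 17-library fit by 3.10 and 1.99. The apoptosis inhibitor birc5b rose by 5.96, with 25600 normalized reads in the library that stood apart, and by 2.92 without it. The immediate-early gene fosb (4.40 ± 1.01, adjusted p = 0.032) and lmo1 (2.85 ± 0.48, adjusted p = 0.0154) passed only in the 17-library fit. The largest falls were those of the tight junction gene cldn15la (-6.58 ± 0.71, adjusted p = 0.00118), the sodium-glucose cotransporter slc5a1 (ENSORLG00000009712, -6.37), the cytochrome P450 cyp2n13 (ENSORLG00000014869, -5.85), the glucose-6-phosphatase g6pca.2 (-5.69) and the kidney cotransporter slc12a1 (-5.65). The adjusted p of slc5a1 was 0.036 from 18 libraries and 0.0555 from 17. In replicates 1, 2 and 3 at 0 mg/L slc5a1 had 3758, 9.71 and 418 normalized reads, cyp2n13 1444, 13.8 and 1197, slc12a1 1033, 26.7 and 1469, cldn15la 1675, 155 and 496 and g6pca.2 2446, 71.2 and 15.5. The first 3 were thus high mainly in the 2 libraries with the gut and kidney transcripts, and g6pca.2 in replicate 1 alone. These fitted values depend on the pseudocount, since the genes had under 10 normalized reads on average at 0.002 mg/L.

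In total 1476 genes passed at 0.002 mg/L in the control lineage, 506 higher and 970 lower. Another scaling (TMM) gave 314 higher and 1032 lower. The 17-library fit called 863 genes, 349 higher and 514 lower, of which 544 were also called from 18 libraries. The median difference of all genes was -0.15 from 18 libraries and 0.01 from 17, so the balance of rises and falls moved with that library. Without replicate 1, 2 or 3 of the control lineage at 0 mg/L the count was 3, 721 or 1, and without replicate 1 of the 0.002 mg/L group it was 5527. The 17-library count of 863 became 4, 1401 and 39 without the same 3 libraries at 0 mg/L. A fit to the 6 libraries of these groups alone called 0 genes with limma, where 18 libraries gave 6174 genes at an unadjusted p under 0.05, edgeR called 3116 and DESeq2 4733.

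Gene lists fixed beforehand were tested at 0.002 mg/L, each with camera against all other genes, and most members of each list did not pass singly. Of 29 pancreas, gut and kidney genes 13 fell (18 adjusted over the list alone), with a median of -2.79 (adjusted p = 2.26e-06, and 0.188 with an estimated correlation). This list was high in replicates 1 and 3 of the 0 mg/L group, as given above. Of 18 xenobiotic metabolism genes 5 fell (6 adjusted over the list alone), median -1.10 (adjusted p = 0.000848, and 0.228 with an estimated correlation). They included the cytochromes P450 cyp1c2 (315 ± 62.1 to 49.9 ± 31.7) and cyp3a40 (1394 ± 1216 to 58.5 ± 35.6). The list level was 1.07, -0.07 and 0.50 in replicates 1, 2 and 3 of the 0 mg/L group, and cyp3a40 had 2561, 135 and 1486 normalized reads there, so both were high in the 2 libraries with the gut and kidney transcripts. Of 18 Sertoli cell genes 4 fell (11 adjusted over the list alone), median -1.45 (adjusted p = 6.44e-05, and 0.236 with an estimated correlation). Among them was the tight junction gene cldn11a, from 2939 ± 485 to 450 ± 578. The steroid and thyroid receptors had 6 of 22 genes lower and a median of -1.35 (adjusted p = 0.00138, and 0.188 with an estimated correlation); nr2f1a fell from 160 ± 14.8 to 34.0 ± 13.8. Muscle and connective tissue genes had 12 of 34 lower and a median of -1.47 (adjusted p = 1.17e-05, and 0.188 with an estimated correlation); fibronectin fn1b fell from 1314 ± 580 to 132 ± 81.9. The lipoproteins and liver plasma proteins (2 of 17 lower, median -1.67, adjusted p = 0.00187) gave adjusted p = 0.202 with an estimated correlation, and apolipoprotein apoeb fell from 6583 ± 2658 to 940 ± 938. In the 17-library fit these 6 lists were called in the same direction, with medians from -0.68 for xenobiotic metabolism to -2.07 for the pancreas, gut and kidney list, and adjusted p from 0.122 to 0.247 with an estimated correlation.

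Other lists at this dose had medians nearer 0 or of the other sign without the library that stood apart. The spermatid and flagellum list (2 of 49 lower) had a median of -0.78 from 18 libraries (adjusted p = 0.00385, and 0.685 with an estimated correlation) and 0.20 from 17 (adjusted p = 0.0412, and 0.834 with an estimated correlation). The oocyte and ovary list had a median of 2.88 from 18 (0 of 14 past the threshold for single genes, adjusted p = 0.0236, and 0.544 with an estimated correlation) and -0.03 from 17. The cytosolic ribosomal proteins had 0.38 (0 higher and 1 lower of 66, adjusted p = 2.79e-05, and 0.561 with an estimated correlation) and 0.02. Oxidative phosphorylation genes (5 of 64 higher) had 0.68 from 18 (adjusted p = 1.61e-09, and 0.335 with an estimated correlation) and 0.32 from 17 (adjusted p = 0.000183, and 0.633 with an estimated correlation). Cell cycle genes (2 of 47 higher) had 0.54 (adjusted p = 4.61e-05, and 0.188 with an estimated correlation) and 0.31 (adjusted p = 0.00109, and 0.283 with an estimated correlation). The spermatogonial marker id4 fell by 3.12 and the histone deacetylase HDAC2 rose by 1.26, both members of lists without a call. The estrogen receptor esr1, a member of the receptor list above, fell from 18 libraries (-3.01, adjusted p = 0.0304) and from 17 (-2.11, adjusted p = 0.0472). The 17-library fit called 2 more lists, the piRNA pathway (median 0.26, adjusted p = 0.0075) and meiotic prophase (0.40, adjusted p = 0.00307), with adjusted p = 0.482 and 0.437 with an estimated correlation.

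The second comparison concerned 0.02 mg/L in the control lineage. From 18 libraries 13 genes passed, 2 higher and 11 lower, and from 17 libraries 2409 passed, 1155 higher and 1254 lower, the 13 included. Named falls in both fits were S100P (839 ± 695 to 0.235 ± 0.408), cyp2n13 (ENSORLG00000014869, 885 ± 765 to 1.03 ± 1.06), cldn15la (776 ± 797 to 4.36 ± 1.31) and the antiproliferative gene btg1 (936 ± 426 to 131 ± 64.9). The adjusted p of cldn15la was 0.00116 from 18 libraries and 0.000643 from 17. At 0 mg/L replicates 1, 2 and 3 had 1371, 52.6 and 1094 normalized reads of S100P, 1444, 13.8 and 1197 of cyp2n13, 1675, 155 and 496 of cldn15la and 817, 582 and 1408 of btg1, so the first 2 were high mainly in the 2 libraries with the gut and kidney transcripts. The sperm flagellum gene cfap43 fell in the 17-library fit (-1.52 ± 0.26, adjusted p = 0.00658). The Sertoli hormone gene amh (ENSORLG00000015951, -1.25 ± 0.26, adjusted p = 0.012) and the retinoid receptor rxrbb (-1.46 ± 0.30, adjusted p = 0.011) fell too. The other gene with the symbol amh (ENSORLG00000005044) overlapped between the groups. It had 1715, 1734 and 1278 normalized reads in replicates 1, 2 and 3 at 0 mg/L, and 892, 1880 and 1366 at 0.02 mg/L. The cyclin ccne1 rose by 1.07 ± 0.21 (adjusted p = 0.00969), HDAC2 by 1.15 ± 0.23 (adjusted p = 0.0101) and c-fos by 4.33 ± 1.23 (adjusted p = 0.0394), to 1268 ± 251 normalized reads. Egg-coat genes were among the largest rises in that fit, zp3f.1 (27.0 ± 29.2 to 1019 ± 1082), zp3f.2 (7.66 ± 6.88 to 298 ± 297) and zpax1 (66.2 ± 28.8 to 1107 ± 1338). The quinone reductase nqo1 rose beside them, from 57.6 ± 13.7 to 476 ± 264, and the oocyte gene org from 109 ± 16.5 to 596 ± 336. All 5 were also abundant in the library that stood apart, and zp3f.1 and zp3f.2 may share reads.

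At 0.02 mg/L the pancreas, gut and kidney list again had the lowest median, -2.34 (0 of 29 past the threshold from 18 libraries, 15 lower adjusted over the list alone, adjusted p = 3.98e-07, and 0.326 with an estimated correlation). From 17 libraries 14 of its genes fell and 1 rose. The xenobiotic list had -0.99 (adjusted p = 0.00179), the steroid and thyroid receptors -0.95 (0.00439), the lipoproteins -0.94 (0.00716), the Sertoli cell list -0.79 (0.00841) and the muscle list -0.63 (0.00848). With an estimated correlation these adjusted p were 0.326, 0.326, 0.326, 0.538 and 0.453. Oxidative phosphorylation (0.28, adjusted p = 0.00361), the cell cycle (0.29, 0.00841), the piRNA pathway (0.26, 0.0495) and cytosolic ribosomal proteins (0.19, 0.0199) had positive medians, with adjusted p = 0.744, 0.453, 0.549 and 0.816 with an estimated correlation. In the 17-library fit 9 of 47 cell cycle genes were higher and 1 lower, and the piRNA call was lost (adjusted p = 0.0872). The oocyte and ovary list was called in that fit alone, with a median of 0.87 (2 of 14 higher, adjusted p = 0.00906, and 0.319 with an estimated correlation). Its level was -0.05, 1.07 and 0.83 in the 3 libraries at 0.02 mg/L.

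The 18-library count of 13 at 0.02 mg/L rested on single libraries. It was 1, 173 and 5 without replicates 1, 2 and 3 at 0 mg/L, and 3, 157 and 1 without those at 0.02 mg/L. The 17-library count of 2409 became 84, 1883 and 956 without the same 3 libraries at 0 mg/L, and 555, 3114 and 77 without those at 0.02 mg/L. Across genes, which are not independent replicates, the responses at 0.002 and 0.02 mg/L correlated in the control lineage (r = 0.727, rho = 0.683 from 18 libraries, r = 0.808 from 17). Shared controls alone gave 0.501 and 0.449 in simulations that drew each gene on its own, and the covariance was 0.815 against a simulated 0.199. In the 17-library fits 272 genes rose and 289 fell at both doses, where independent lists would share 21.5 and 34.3, and 0 went opposite ways. The 3 controls could not be divided so that each part kept 2 libraries, so part of that excess may come from sharing them. A test for any PFOS effect over both doses called 64 genes from 18 libraries and 1526 from 17. The 64 became 1, 258 and 3 without replicates 1, 2 and 3 at 0 mg/L, 3138 and 36 without replicates 1 and 3 at 0.002 mg/L, and 6, 266 and 3 without the replicates at 0.02 mg/L. The 1526 became 23, 1319 and 228 without those at 0 mg/L and 528, 2468 and 340 without those at 0.02 mg/L.

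In the BPA lineage the same concentrations called fewer genes. At 0.002 mg/L limma called 0 genes, with 715 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 10. The 17-library fit called 0 as well, with 1795 at an unadjusted p under 0.05. The complement gene c3-2 (192 ± 88.0 to 47.1 ± 17.9) and the neutrophil oxidase subunit ncf1 (376 ± 133 to 73.1 ± 55.4) were among the 5 named genes with the smallest p. The others, ap5s1, retreg2 and sumo4, had positive differences, of 1.90 for retreg2 and 1.59 for sumo4. None passed, and from 17 libraries their adjusted p was 0.43. The leukocyte list had a median of -0.79 (0 of 31 past the threshold, adjusted p = 2.3e-05) and the muscle list -0.50 (0 of 34, 4.72e-05). Cytosolic ribosomal proteins had -0.25 (0 of 66, 1.05e-05) and oxidative phosphorylation -0.23 (0 of 64, 0.00408). With an estimated correlation the adjusted p of these 4 lists were 0.616, 0.59, 0.676 and 0.676. From 17 libraries these 4 were called again (adjusted p from 0.38 to 0.614 with an estimated correlation), and meiotic prophase and the spermatid list beside them (medians 0.07 and 0.10, adjusted p = 0.0117 and 0.00659, and 0.614 for both with an estimated correlation). The 17-library count of 0 became 1 without replicate 1 at 0 mg/L or replicate 2 at 0.002 mg/L.

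At 0.02 mg/L in the BPA lineage limma called 0 genes from 18 libraries, with 1596 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 144. The named genes with the smallest p there, actl6a (1.90), rgma (1.88), ap5s1 (1.65), socs6 (2.90) and rxrbb (1.61), had adjusted p = 0.408 and did not pass. From 17 libraries limma called 77, 67 higher and 10 lower, and edgeR 0. The named rises in that fit included socs6, a suppressor of cytokine signalling (26.9 ± 10.2 to 215 ± 117), the ciliary transcription factor rfx2 (243 ± 113 to 922 ± 111) and the cytokinesis gene racgap1 (544 ± 236 to 1881 ± 404). The chromatin remodelling subunit actl6a (258 ± 44.9 to 978 ± 247), amh (ENSORLG00000015951, 7719 ± 682 to 20577 ± 3177) and the meiotic cohesin smc1b (2989 ± 367 to 8283 ± 1273) also rose. The other amh gene (ENSORLG00000005044) had 1427, 1293 and 1395 normalized reads at 0 mg/L and 1683, 1771 and 1321 at 0.02 mg/L. The steroid enzyme gene cyp17 fell from 11380 ± 3826 to 2819 ± 394 and the smooth muscle gene tagln from 8360 ± 1396 to 2978 ± 812. Adjusted p in this fit ranged from 0.0348 to 0.0465 over the genes named as rising or falling. Without replicates 1, 2 and 3 of the control lineage at 0 mg/L, which lend only their spread here, the count of 77 became 15, 0 and 12. Without replicates 1, 2 and 3 of the BPA lineage at 0 mg/L it was 1, 0 and 145, and without those at 0.02 mg/L it was 292, 2 and 682. A test for any PFOS effect in this lineage called 0 genes with limma from 18 libraries (851 at an unadjusted p under 0.05) and 0 from 17, with edgeR at 0 and DESeq2 at 29. The 0 from 17 became 1 without replicate 1 at 0 mg/L or replicate 2 at 0.002 mg/L and 112 without replicate 3 at 0.02 mg/L.

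Gene groups at 0.02 mg/L in the BPA lineage had medians of 0.21 for meiotic prophase (adjusted p = 0.00361), 0.34 for the piRNA pathway (0.00297), 0.18 for the unfolded protein response (0.0297) and 0.11 for the cell cycle (0.0493). With an estimated correlation these became adjusted p = 0.832, 0.59, 0.514 and 0.681. Lower medians were those of the pancreas, gut and kidney list (-0.83, adjusted p = 0.00297), the muscle list (-0.60, 0.000935) and the leukocyte list (-0.58, 0.00297). These became adjusted p = 0.681, 0.514 and 0.681 with an estimated correlation. None of their members passed singly from 18 libraries. From 17 libraries the same 7 lists were called (adjusted p from 0.464 to 0.62 with an estimated correlation), and the spermatid list as well (0.12, adjusted p = 0.0216, and 0.864 with an estimated correlation). The spermatid level was -0.08, -0.31 and 0.49 in replicates 1, 2 and 3 at 0.02 mg/L, against -0.21, -0.01 and -0.11 at 0 mg/L. Only replicate 3 thus lay above the range at 0 mg/L.

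Without PFOS the comparison asked how the testis differed between the lineages. With 2 lineages in all, an effect of the ancestral exposure cannot be told apart from other differences between them. From 18 libraries 4 genes were lower and 0 higher in the BPA lineage: cldn15la (776 ± 797 in the control and 9.45 ± 3.15 in the BPA lineage), rfx2 (2148 ± 455 and 243 ± 113), the axon guidance gene rgma (450 ± 99.5 and 70.6 ± 3.35) and an unnamed gene (ENSORLG00000015322, 764 and 154). Their adjusted p were 0.00946, 0.0468, 0.041 and 0.041. Next by p among named genes were sumo4 (-2.68) and socs6 (-3.58), which did not pass (adjusted p = 0.0635 for both). From 17 libraries 1927 genes passed, 806 higher and 1121 lower, the 4 included. The meiotic genes sycp1 (8099 ± 3975 in the control and 1759 ± 740.0 in the BPA lineage, difference -2.19) and smc1b (-1.53) and the flagellar gene cfap43 (-1.48) were lower in that fit. Their lists were not called: meiotic prophase had 5 of 24 genes lower and a median of 0.19 (adjusted p = 0.589), and the spermatid list 4 of 49 lower and -0.09 (adjusted p = 0.203). Also lower were amh (ENSORLG00000015951, -1.49 ± 0.26, adjusted p = 0.00481), rxrbb (-1.74 ± 0.30, adjusted p = 0.00463) and uhrf1, which maintains DNA methylation (-1.30 ± 0.24, adjusted p = 0.00633). The other amh gene (ENSORLG00000005044) had 1715, 1734 and 1278 normalized reads in the control and 1427, 1293 and 1395 in the BPA lineage. Higher genes included c-fos (4.18 ± 1.23, adjusted p = 0.048), whose BPA lineage libraries ranged from 165 to 4751, birc5b (3.82 ± 0.57, adjusted p = 0.00295), the growth factor egf (3.44 ± 0.90, adjusted p = 0.0262) and the developmental factors pax2b (3.24 ± 0.70, adjusted p = 0.0122) and lbx1b (3.11 ± 0.81, adjusted p = 0.027).

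Without PFOS, the xenobiotic list had a median difference of -0.93 (0 of 18 past the threshold from 18 libraries, 8 lower and 1 higher adjusted over the list alone, adjusted p = 0.000418). The pancreas, gut and kidney list had -1.27 (0 of 29, adjusted p = 0.00425) and the receptors -0.50 (0 of 22, adjusted p = 0.00935). Ribosomal proteins had 0.35 (0 of 66, adjusted p = 0.000212) and oxidative phosphorylation 0.29 (0 of 64, adjusted p = 0.00671). With an estimated correlation the 5 adjusted p were 0.546, 0.793, 0.546, 0.944 and 0.944. The same 5 lists were called from 17 libraries, with adjusted p from 0.661 to 0.882 with an estimated correlation. The pancreas, gut and kidney level of 1.43, 0.12 and 1.26 in control replicates 1, 2 and 3 compares with 0.28, -0.07 and 0.44 in the BPA lineage, and the xenobiotic level of 1.07, -0.07 and 0.50 with 0.01, -0.16 and -0.18, so in both lists control replicate 2 lay inside the range of the BPA lineage. The count of 4 became 0, 128 and 0 without replicates 1, 2 and 3 of the control lineage and 0 without any 1 replicate of the BPA lineage. The 17-library count of 1927 became 291, 1664 and 978 without the same control replicates and 536, 180 and 2776 without replicates 1, 2 and 3 of the BPA lineage. TMM scaling called 84 genes, edgeR 1 and DESeq2 1338. The response to 0.02 mg/L in the control lineage and the lineage difference without PFOS correlated across genes (r = 0.759, rho = 0.751). The controls they share gave 0.499 in simulations that drew each gene on its own, and the covariance was 0.661 against a simulated 0.198. In the 17-library fits 446 genes were higher in both and 661 lower in both (49.5 and 74.8 for independent lists), and 0 were opposite. The 2 comparisons share the 3 controls, so part of that overlap may come from sharing them.

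At 0.002 mg/L limma called 0 genes between lineages from 18 libraries, with 2829 at an unadjusted p under 0.05, and 0 from 17, with 1583. edgeR called 0 in both, and DESeq2 804 from 18 libraries. The named genes with the smallest p were arrb1 (3.02, adjusted p = 0.193), gpr1 (3.30, 0.193), pdgfra (1.76, 0.197), hpdb (3.51, 0.197) and slc16a12a (2.75, 0.201). Without replicate 1 of the control lineage, which leaves the library that stood apart as 1 of 2, the count was 992, and without replicate 3 it was 1. The 17-library count of 0 became 1 without replicate 1 of the control lineage at 0 mg/L. Of 12 list calls from 18 libraries, the Sertoli list (median 1.37, adjusted p = 4.88e-05), the muscle list (0.84, 0.000128), the receptors (0.61, 0.0447) and oxidative phosphorylation (-0.57, 2.94e-12) were also called from 17 with the same direction. Their adjusted p with an estimated correlation were 0.371, 0.371, 0.429 and 0.429. The spermatid list (0.83, adjusted p = 0.000125) and the meiotic list (0.50, 0.0457) turned to -0.22 and -0.22 from 17 libraries, and gave adjusted p = 0.585 and 0.704 with an estimated correlation. The oocyte list (-2.47, adjusted p = 0.00751, and 0.549 with an estimated correlation) turned to 0.42. The remaining calls, for the pancreas, gut and kidney list (1.08), NRF2 targets (-0.43), the cell cycle (-0.40), ribosomal proteins (-0.29) and the unfolded protein response (-0.28), were not made from 17 libraries. Their adjusted p with an estimated correlation were 0.485, 0.429, 0.371, 0.585 and 0.371. The median difference of all genes was 0.14 from 18 libraries and -0.02 from 17.

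At 0.02 mg/L 3 genes differed between lineages from 18 libraries, all higher in the BPA lineage and none with a gene name. They are listed because the count is small, and were chosen after their values were seen. ENSORLG00000000970 had 0.235 normalized reads in the control and 341 in the BPA lineage (7.43, adjusted p = 0.00594). ENSORLG00000026074 had 1.21 and 151 (6.18, adjusted p = 0.00594), and ENSORLG00000007279 497 and 9500 (4.25, adjusted p = 0.0081). The named genes with the smallest p did not pass: ap2s1 (1.998, adjusted p = 0.63), ptprt (-3.75, 0.661), rassf6 (3.82, 0.663), pdik1l (-1.89, 0.663) and trim46b (-2.18, 0.729). The 17-library fit called these 3 and ENSORLG00000025835, which was lower. The count of 3 became 0 without replicate 2 and 1 without replicate 1 or 3 of the BPA lineage, and 1 without replicate 1 of the control lineage. The 17-library count of 4 became 362 without replicate 2 and 6 without replicate 1 of the control lineage, and 6 without replicate 3 of the BPA lineage. The unfolded protein response list had a median of 0.17 (0 of 30 past the threshold, adjusted p = 0.0208) and ribosomal proteins 0.22 (0 of 66, adjusted p = 9.97e-05), with adjusted p = 0.509 and 0.971 with an estimated correlation. The ribosomal level was -0.16, 0.09 and 0.77 in BPA lineage replicates 1, 2 and 3, and without replicate 3 the list had no call and its median turned to -0.06. Averaged over doses 5 genes were higher in the BPA lineage from 18 libraries, the 3 above, ENSORLG00000025978 and the Nogo receptor relative rtn4rl2b (2.07 ± 0.34, adjusted p = 0.0483). The last had 22.5 ± 4.50 normalized reads in the control and 160 ± 61.2 in the BPA lineage without PFOS, 19.97 ± 14.04 and 45.9 ± 14.8 at 0.002 mg/L, where the libraries overlapped, and 16.4 ± 7.10 and 82.8 ± 43.0 at 0.02 mg/L. The 17-library fit called 9 genes, 6 higher and 3 lower, these 5 included. That count was 36 without replicate 2 and 5 without replicate 1 of the control lineage at 0 mg/L, 3 without replicate 2 of the BPA lineage at 0.002 mg/L and 5 without its replicate 1 there or replicate 2 at 0 mg/L. The count of 5 became 2 without replicate 2 of the control lineage at 0.02 mg/L. Without replicates 1, 2 and 3 of the BPA lineage it was 2, 3 and 2 at 0 mg/L and 2 each at 0.002 mg/L, and 3 without replicate 1 or 3 at 0.02 mg/L. Of 6 lists called on average from 18 libraries, none had a member past the threshold. They were oxidative phosphorylation (-0.11, adjusted p = 0.000513), muscle (0.27, 0.000615), Sertoli cells (0.43, 0.00195), NRF2 targets (-0.15, 0.00506), spermatids (0.21, 0.0229) and oocyte and ovary (-0.73, 0.046). Their adjusted p with an estimated correlation lay between 0.915 and 0.927. From 17 libraries the spermatid list turned to -0.08 and the oocyte list to 0.03, oxidative phosphorylation and NRF2 targets were not called, and ribosomal proteins were (0.17, adjusted p = 1.57e-11, and 0.948 with an estimated correlation).

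Whether the lineages responded differently to PFOS was tested with the interaction of lineage and dose. At 0.02 mg/L 261 genes differed from 18 libraries, 215 with a higher response in the BPA lineage and 46 with a lower one, and 2674 from 17 libraries (1483 and 1191), the 261 included. The retinoid receptor rxrbb went from 1362 ± 137 to 532 ± 258 in the control and from 418 ± 128 to 1247 ± 127 in the BPA lineage (difference of responses 3.07 ± 0.51, adjusted p = 0.0218). The same crossing was seen in rfx2 (2148 ± 455 to 349 ± 169, and 243 ± 113 to 922 ± 111, difference 4.79 ± 0.73) and socs6 (323 ± 76.6 to 52.95 ± 41.73, and 26.9 ± 10.2 to 215 ± 117, difference 5.74 ± 0.90). It was also seen in the p53 target ccng1 (3.71 ± 0.64), the glucocorticoid receptor nr3c1 (ENSORLG00000006022, 2.65 ± 0.61), uhrf1 (1.97 ± 0.37) and the unfolded protein response genes ddit3 (3.33 ± 0.77) and dnajc3b (2.47 ± 0.51). The deubiquitinase usp10 (4.46), the lysosomal gene lamp2 (4.13), the Wnt receptor fzd7b (4.43) and the prion protein gene prnpb (5.05) were among the other large positive differences. For cldn15la (5.67 ± 1.01) both responses went the same way, from 776 ± 797 to 4.36 ± 1.31 and from 9.45 ± 3.15 to 4.62 ± 2.01. Genes with a lower response in the BPA lineage included the transcription factors sp5a (115 ± 54.2 to 442 ± 111, and 534 ± 253 to 168 ± 65.7, difference -3.61) and tal2 (-2.84). The cation transporter slc22a2 (-3.28), the spliceosome gene snrpb2 (-2.01) and the mRNA export gene ALYREF (-1.85) were others. Among respiratory genes cox4i2 passed (-1.38 ± 0.32, adjusted p = 0.0451). In control lineage replicates 1, 2 and 3 mitochondrial mRNA took 2.20%, 1.96% and 3.28% of reads at 0 mg/L. At 0.02 mg/L it took 4.50%, 2.41% and 4.11%. In the BPA lineage the shares were 4.21%, 5.78% and 2.43% at 0 mg/L, and 3.12%, 2.42% and 3.72% at 0.02 mg/L. The libraries overlapped within each lineage. Whether sample composition or quality contributes to the interaction was not tested.

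**Figure D2:**
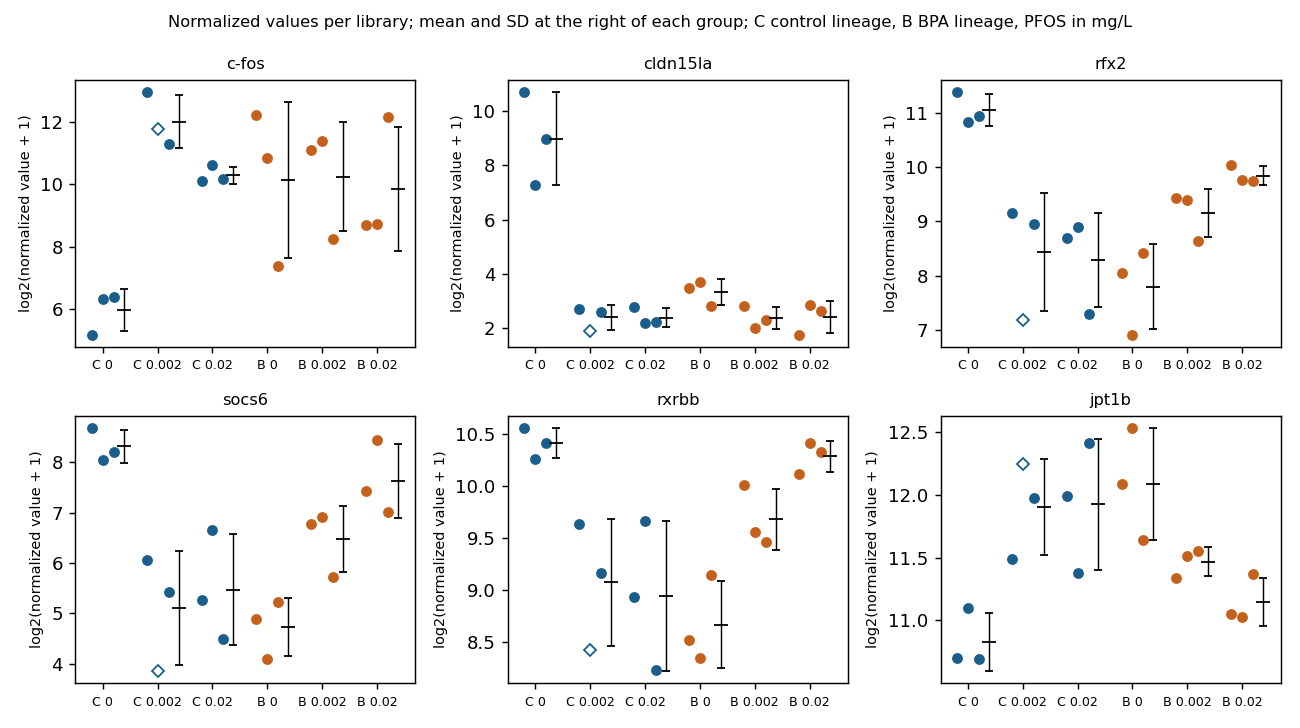
Normalized values of 6 genes per library as log2(value + 1) on the y axis, with mean and SD at the right of each of the 6 groups on the x axis (C control lineage, B BPA lineage, PFOS in mg/L) and the library that stood apart as an open diamond. The genes rfx2, socs6 and rxrbb were lower at 0.02 than at 0 mg/L in the control lineage and higher in the BPA lineage, jpt1b went the other way, and cldn15la was high in the control lineage at 0 mg/L alone.

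In the 17-library fit amh (ENSORLG00000015951, 2.66 ± 0.36, adjusted p = 0.00117), cfap43 (2.63 ± 0.36, adjusted p = 0.0012) and smc1b (2.56 ± 0.43, adjusted p = 0.00253) also had positive differences of response at 0.02 mg/L. In the other amh gene (ENSORLG00000005044) the libraries at 0 and 0.02 mg/L overlapped in each lineage. Across genes the responses of the lineages to 0.02 mg/L correlated negatively (r = -0.191, rho = -0.255), where no library is shared and simulations gave -0.000571. The covariance was -0.132, against a simulated -0.000227. Genes are not independent replicates. The simulations drew each gene on its own, so their value near 0 does not show how far r can lie from 0 when genes vary together. Of the 1155 genes that rose in the control lineage in the 17-library fit, 887 had lower means at 0.02 than at 0 mg/L in the BPA lineage (median -0.22, against 0.87 in the control lineage). Of the 1254 that fell, 910 had higher means in the BPA lineage (median 0.59 against -1.61), while 54.4% of all genes were lower there. Those medians rest on genes selected in the control lineage, which inflates the control values. Of the 77 genes called in the BPA lineage 48 were called in the opposite direction in the control lineage and 3 in the same one.

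**Figure D3:**
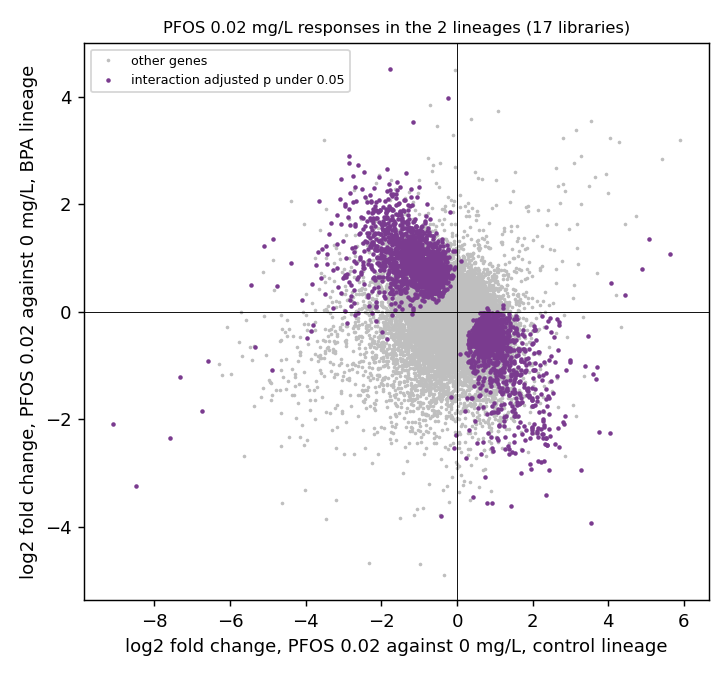
Log2 difference of 0.02 against 0 mg/L PFOS per gene in the control lineage (x axis) and in the BPA lineage (y axis), from the 17-library fits, with genes whose responses differed (adjusted p under 0.05 for the interaction) in colour. Of the 2674 coloured genes 1483 had a higher response in the BPA lineage. Genes at upper left or lower right have 2 responses of opposite sign.

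Lists called for the interaction at 0.02 mg/L were xenobiotic metabolism (0 of 18 past the threshold, median 1.60, adjusted p = 0.0101), the receptors (2 of 22 higher, 0.72, adjusted p = 0.0486), the unfolded protein response (2 of 30 higher, 0.28, adjusted p = 0.0486) and oxidative phosphorylation (1 of 64 lower, -0.37, adjusted p = 0.0383). With an estimated correlation these became adjusted p = 0.622, 0.622, 0.622 and 0.948. From 17 libraries only xenobiotic metabolism was called (adjusted p = 0.0408, and 0.644 with an estimated correlation), and the other 3 had adjusted p = 0.141, 0.0677 and 0.0548. The xenobiotic level in the untreated control replicates (1.07, -0.07 and 0.50) followed that of the pancreas, gut and kidney list (1.43, 0.12 and 1.26), high in replicates 1 and 3. The median over all genes was -0.10, and 0.05 with TMM scaling, which called 465 higher and 45 lower. The count of 261 was 0, 166 and 2 without replicates 1, 2 and 3 of the control lineage at 0 mg/L and 1, 838 and 2 without those at 0.02 mg/L. It was 1, 1 and 360 without the BPA lineage replicates at 0 mg/L and 107, 2 and 753 without those at 0.02 mg/L. The 17-library count of 2674 became 1389, 2672 and 2127 without replicates 1, 2 and 3 of the control lineage at 0 mg/L and 1574, 3753 and 1149 without those at 0.02 mg/L. Without the BPA lineage replicates it was 1677, 1259 and 3300 at 0 mg/L and 2639, 1606 and 4016 at 0.02 mg/L.

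At 0.002 mg/L limma found 0 genes with an interaction from 18 libraries, with 4107 at an unadjusted p under 0.05, edgeR found 0 and DESeq2 1689. The named genes with the smallest p, sumo4 (3.79), cldn15la (5.63), socs6 (4.94), rfx2 (3.97) and appbp2 (2.45), had adjusted p = 0.073 and did not pass. From 17 libraries 169 passed, 117 with a higher and 52 with a lower response in the BPA lineage, and edgeR found 57. They included socs6 (4.31 ± 0.80, adjusted p = 0.034), rfx2 (3.35 ± 0.59, adjusted p = 0.0315), cldn15la (5.37 ± 1.04, adjusted p = 0.0348), the uridylyltransferase tut4 (3.28 ± 0.59, adjusted p = 0.0315), cyp1c2 (2.88 ± 0.62, adjusted p = 0.0478) and birc5b (-4.37 ± 0.86, adjusted p = 0.0362). The 17-library count of 169 was 0, 539 and 52 without replicates 1, 2 and 3 of the control lineage at 0 mg/L. Without the BPA lineage replicates it was 0, 0 and 1196 at 0 mg/L and 0, 0 and 6 at 0.002 mg/L. The 18-library count of 0 was 24 without replicate 2 at 0 mg/L and 2094 and 1 without replicates 1 and 3 at 0.002 mg/L. Of the 10 lists called from 18 libraries, the pancreas, gut and kidney list (2.64), the Sertoli list (1.63), the receptors (1.38), xenobiotic metabolism (1.26), ribosomal proteins (-0.69) and oxidative phosphorylation (-0.90) were also called from 17. The spermatid list (1.03), the lipoproteins (1.78), the muscle list (0.72) and the cell cycle (-0.57) were not. The adjusted p of the 10 ran from 5.13e-10 for oxidative phosphorylation to 0.0476 for the lipoproteins, and with an estimated correlation from 0.462 for the receptors to 0.713 for the spermatid list.

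**Figure D4:**
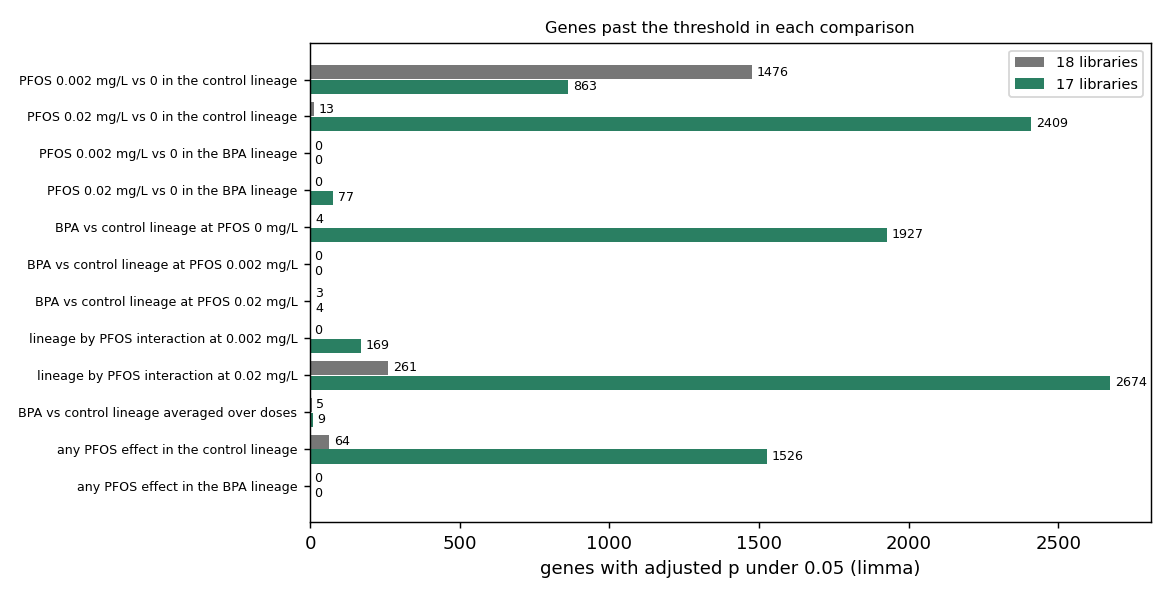
Number of genes with adjusted p under 0.05 (x axis, limma) in each of the 12 comparisons, from 18 libraries (grey) and from the 17 without the library that stood apart (green). The count at 0.02 mg/L in the control lineage is 13 in grey and 2409 in green, and the interaction at 0.02 mg/L is 261 and 2674.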

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

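The tests of the library that stood apart, of the untreated control group and of oocyte transcripts, and the splits counted over gene lists, were chosen after the results were seen, as were all 17-library fits.

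The response to 0.02 mg/L PFOS differed between the lineages by the interaction test in 261 genes from 18 libraries and 2674 from 17, and the response to 0.002 mg/L in 169 from 17. Positive differences, BPA minus control lineage on the log2 scale, were those of socs6 (5.74), cldn15la (5.67), prnpb (5.05), rfx2 (4.79), stk38l (4.73), usp10 (4.46), fzd7b (4.43), OSBP2 (4.31), fam102bb (4.18) and lamp2 (4.13). Members of the gene lists with positive differences were ccng1 (3.71), ddit3 (3.33), rxrbb (3.07), nr3c1 (2.65), dnajc3b (2.47) and uhrf1 (1.97). Negative ones were those of sp5a (-3.61), vsig10l (-3.29), slc22a2 (-3.28), tal2 (-2.84), pla2g7 (-2.38), SMCO4 (-2.30), jpt1b (-2.03), snrpb2 (-2.01), tas1r2 (-1.99), ALYREF (-1.85) and cox4i2 (-1.38).

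Other splits of the libraries were fitted in the same way. For the interaction at 0.02 mg/L, 1 of 100 splits, the real one, gave as many as 261 genes (highest other 1). From 17 libraries 1 of 100 gave as many as 2674 (highest other 1527). For the interaction at 0.002 mg/L from 17 libraries 1 of 100 gave 169 (highest other 2). From 18 libraries, with 0 genes, 100 of 100 gave as many (highest other 1). These splits shuffled lineage and dose together, so they test for any difference among the groups and not for the interaction alone. Over the lists 42 of 100 splits gave as many as the 10 calls at 0.002 mg/L (highest other 16) and 66 of 100 as many as the 4 at 0.02 mg/L (highest other 14), so chance is not excluded for them. For the average lineage difference 1 of 100 splits gave 5 genes (highest other 1) and from 17 libraries 2 of 100 gave 9 (highest other 349). A count above the real 9 thus also arose in another split (349), and the reason was not tested. The 6 lists of the average lineage difference were matched by 74 of 100 splits (highest other 11). For any PFOS effect 3 of 100 splits gave as many as 64 genes in the control lineage (highest other 79) and 3 of 100 as many as 1526 from 17 libraries (highest other 2228), and in the BPA lineage 100 of 100 gave as many as 0 (highest other 0).

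Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. In the control lineage at 0.002 mg/L 1 split gave 1476 genes (highest other 57), and from 17 libraries 1 gave 863 (highest other 419). At 0.02 mg/L 1 gave 13 (highest other 1), and from 17 libraries 1 gave 2409 (highest other 1). In the BPA lineage all 10 gave as many as the 0 called at 0.002 mg/L and the 0 called at 0.02 mg/L (highest other 0), and from 17 libraries 2 gave as many as 77 at 0.02 mg/L (highest other 1186). Between lineages 1 gave 4 without PFOS (highest other 0; from 17 libraries 1 gave 1927, highest other 1). At 0.002 mg/L 10 gave as many as 0 (highest other 2), and at 0.02 mg/L 1 gave 3 (highest other 1; from 17 libraries 3 gave as many as 4, highest other 426). Counts above the real 77 and 4 thus also arose in other splits (1186 and 426), and the reason was not tested. Over the lists the splits with as many calls numbered 3 for the control lineage at 0.002 mg/L (11 calls, highest other 13) and 2 at 0.02 mg/L (10, highest other 10). They numbered 4 (4, highest other 5) and 5 (7, highest other 8) in the BPA lineage, and 5 (5, highest other 7), 1 (12, highest other 10) and 8 (2, highest other 5) between lineages in order of dose.

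The library labelled control lineage PFOS 0.002 replicate 2 stood apart. Its 27.4 M recovered reads lay inside the range of the other 17, which argues against depth. The other 2 libraries of its group had oocyte and ovary list levels of at most -0.41, which argues against PFOS at this dose as the source of its oocyte transcripts. Its own level was 8.46 (highest other 1.07, SD of the others 0.47), which is consistent with RNA of an ovary or of oocytes in that sample. A mixed or mislabelled sample and an intersex gonad stay open.

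The control lineage libraries without PFOS, the reference of the interaction, differed from the other groups. All 3 had recovered reads in the range of the other 14, which argues against depth. If gut tissue in replicates 1 and 3 alone were the source, replicate 2 with its lower gut list level would be expected to deviate either way. Replicate 2 was not free of such transcripts, though. It had 155 normalized reads of cldn15la (at most 12.2 outside this group) and 316 of ela2l. Its slc5a1 (ENSORLG00000009712) and cyp2n13 (ENSORLG00000014869) were low, at 9.71 and 13.8. Replicate 2 is thus no gut-free comparison. Of 850 genes higher at 0.02 mg/L in a fit without replicate 2, 92% deviated the same way in it. The median was 0.41 against 0.69 in replicates 1 and 3, so their difference was not confined to those 2 libraries. Only 1 of the 850 was on the pancreas, gut and kidney list, so they cannot decide on gut tissue, which would add its own transcripts. For 1033 genes that were lower the values were 79.6% and 0.62 against 1.48, so gut tissue may account for part of them and cannot be told apart from a difference of this group, such as one of lineage and dose.

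Oocyte transcripts were also higher on average in the 6 libraries at 0.02 mg/L, with a mean list level of 0.37 against -0.22 in the 11 others. Not all 6 were raised. In replicate 1 at 0.02 mg/L the level was -0.05 in the control and -0.29 in the BPA lineage. Replicate 1 of the BPA lineage without PFOS had 0.26. An exact two-sided permutation of doses within lineages gave p = 0.00893. It restates the rise that prompted it, so it decides nothing about an effect of PFOS. By lineage the difference was 1.06 in the control (exact permutation p = 0.0179) and 0.14 in the BPA lineage (exact permutation p = 0.5). Carry-over from the library that stood apart predicts 1 common share for its 40 low-background marker transcripts. These were picked as high in that library and low in every library without PFOS. The chi-square per degree of freedom of such a share was 42.2, 48.3 and 9.71 in replicates 1, 2 and 3 of the control lineage at 0.02 mg/L and from 6.26 to 13.7 in the BPA lineage. It reached 9.07 in libraries without PFOS, in replicate 3 of the BPA lineage. That library had the highest fitted share among them, so it is not shown to be free of carry-over. The control lineage libraries without PFOS had no fitted share. Their values exceeded counting error but lay below those of all 6 libraries at 0.02 mg/L. The choice of markers favours low values in libraries without PFOS, so these are no independent baseline. The 2 highest values at 0.02 mg/L lie far above 9.07 and the lowest does not. The values thus do not decide for the 6 libraries together, and carry-over and an effect of the dose cannot be told apart.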

How the results depend on the processing

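The 17-library fits and their alternatives were chosen after seeing the data, and the other alternatives were set beforehand. Where a value moved, the cause was not tested unless the alternative leaves out libraries.

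In the fit to the compared groups alone, the control lineage had 0 genes at 0.002 mg/L and 1657 at 0.02 mg/L, against 1476 and 13 with all libraries, and 1 gene for any PFOS effect against 64. The BPA lineage had 5 and 4 genes at the same doses and 2 for any effect, against 0 in each. The lineages without PFOS differed in 1892 genes against 4, and the interaction at 0.02 mg/L held 1507 against 261. Of 54 passing pairs of a named gene and a comparison, 35 passed. With the replicate block, which treats equal replicate numbers as a pairing, the counts were 825 at 0.002 mg/L in the control lineage, 1 between lineages without PFOS, 132 for the interaction at 0.02 mg/L, 3 for the average of lineages and 37 for any effect in the control lineage. Residuals of 45 pairs with equal numbers had a median correlation of 0.00122, against 0.00261 in 90 pairs with other numbers. Of the 45, 7 lay over 0.1, and the highest was 0.306. The medians show no general pairing, but a pairing of some samples stays open, since the labels do not say what the numbers mark.

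edgeR called 3116 genes at 0.002 and 66 at 0.02 mg/L in the control lineage, 1 between lineages without PFOS, 1 at 0.02 mg/L, 429 for the interaction at 0.02 mg/L and 1982 for any effect in the control lineage. From 17 libraries edgeR called 691 and 2300 at these doses, 2061 between lineages without PFOS, 57 and 2526 for the interaction at 0.002 and 0.02 mg/L, and 1769 for any effect. DESeq2 called 4733 and 1267 genes in the control lineage, 10 and 144 in the BPA lineage, 1338, 804 and 30 between lineages in order of dose, 111 for their average, 1689 and 1614 for the interaction, and 4219 and 29 for any effect in the control and the BPA lineage.

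A pseudocount of 5 gave 8 genes at 0.02 mg/L in the control lineage and 214 for any effect in it. TMM scaling gave 84 between lineages without PFOS, 5 and 510 for the interaction at 0.002 and 0.02 mg/L and 205 for any effect in the control lineage. Without the filter and with the fold threshold each of the 12 counts stayed within 1.5 times its value. All 71 list calls rested on the preset correlation, and with an estimated correlation 0 remained. From 17 libraries 60 lists were called, and 0 of these with an estimated correlation (lowest adjusted p 0.122).

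Leaving out single libraries of the compared groups, alone or with the library that stood apart, and with it also the untreated control libraries, gave these ranges. Counts ran from 1 to 5527 at 0.002 mg/L and from 1 to 3114 at 0.02 mg/L in the control lineage, and from 0 to 1 and from 0 to 682 in the BPA lineage. Between lineages they ran from 0 to 2776 without PFOS, 0 to 992 at 0.002 mg/L, 0 to 362 at 0.02 mg/L and 2 to 36 on average. They ran from 0 to 2094 and from 0 to 4016 for the interaction at 0.002 and 0.02 mg/L, from 1 to 3138 for any effect in the control lineage and from 0 to 112 for any effect in the BPA lineage.

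List medians that changed sign did so without the library that stood apart, but for 1. The list spermatid and flagellum, PFOS 0.002 mg/L vs 0 in the control lineage, ran from -1.34 to 0.20, and the list oocyte and ovary, PFOS 0.002 mg/L vs 0 in the control lineage, from -0.0334 to 4.40. The list meiotic prophase, BPA vs control lineage at PFOS 0.002 mg/L, ran from -0.22 to 1.03, the list spermatid and flagellum, BPA vs control lineage at PFOS 0.002 mg/L, from -0.22 to 1.39, the list oocyte and ovary, BPA vs control lineage at PFOS 0.002 mg/L, from -3.89 to 0.42 and the list cytosolic ribosomal proteins, BPA vs control lineage at PFOS 0.002 mg/L, from -0.47 to 0.0227. The list spermatid and flagellum, lineage by PFOS interaction at 0.002 mg/L, ran from -0.0387 to 1.57. The list spermatid and flagellum, BPA vs control lineage averaged over doses, ran from -0.0797 to 0.42 and the list oocyte and ovary, BPA vs control lineage averaged over doses, from -1.32 to 0.0325. The list cytosolic ribosomal proteins, BPA vs control lineage at PFOS 0.02 mg/L, ran from -0.0607, without replicate 3 of that group, to 0.40. The correlation of PFOS responses between doses in the control lineage was 0.808 without the library that stood apart, against 0.727.

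No named gene changed direction under any alternative. Of the 54 passing pairs 51 passed with edgeR, 53 with a pseudocount of 5, 49 without the filter, 52 with TMM scaling, 42 with the replicate block and 53 from 17 libraries. Without replicates 1, 2 and 3 of the control lineage at 0 mg/L 3, 43 and 2 of them passed, and without those at 0.02 mg/L 1, 31 and 1 of 32. Without replicates 1, 2 and 3 of the BPA lineage at 0 mg/L 0, 0 and 26 of 31 passed, and without those at 0.02 mg/L 14, 1 and 26 of 28. Of 147 pairs passing from 17 libraries 145 passed with TMM scaling, 141 with a pseudocount of 5, 126 without the filter and 104 with edgeR. Leaving out a library from these fits cost more. Without replicates 1, 2 and 3 of the control lineage at 0 mg/L 37, 120 and 70 of 130 pairs passed, and without those at 0.02 mg/L 39, 50 and 27 of 57. Without replicates 1, 2 and 3 of the BPA lineage at 0 mg/L 38, 31 and 92 passed and 63, 70 and 9 did not, without any 1 at 0.002 mg/L 0 of 26, and without those at 0.02 mg/L 39, 24 and 46 of 47.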

Other observations

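The values below were chosen after they were seen. The marker transcripts of the library labelled control lineage PFOS 0.002 replicate 2 were picked as high in it and low in libraries without PFOS. They took 19.6% of its reads, against 0.0309% to 0.19% in the others, a contrast that this choice favours. That library held 86428 normalized reads of zar1l, 67798 of zp3b, 37021 of btg4, 21627 of bmp15, 12786 of figla and 8783 of gdf9, genes of oocytes. The quinone reductase nqo1 reached 390330. Its gsdf, a gene of somatic gonad cells, stood at 4495 and its sperm flagellum gene spag6 at 1114. All 14 members of the oocyte and ovary list had a mean of at least 10 in the other 17 libraries, and 0 belonged to another list. Of the 29 pancreas, gut and kidney genes 26 had such a mean in the 14 libraries outside the untreated control group and that library.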
